A study of Arabidopsis thaliana with 23 samples.

How the data were processed

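Gene expression was measured in whole seedlings of Arabidopsis thaliana, ecotype Col-0, on 23 Affymetrix ATH1 arrays with 1 biotin-labelled RNA sample per array. Per the labels' protocols and the series' design text, seedlings grew on agar for 6 or 7 days and in shaken liquid medium for 1 day, and were then treated for 3 h. The labels give 9 groups. Arrays numbered 1 to 3 hold mock, 1 µM indole-3-acetic acid (IAA, the main natural auxin), 30 µM kynurenine, 10 µM PEO-IAA and 10 µM PEO-IAA plus 1 µM IAA, with 3 arrays each. Arrays numbered 4 and 5 hold mock, 100 nM IAA, 10 µM PPBo and 10 µM PPBo plus, as labelled, 1 µM IAA, with 2 arrays each. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

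The deposited values are MAS5 probe set signals, a linear intensity per probe set and array, per the submitters' processing notes, which name MAS5 without a version. The 2% trimmed mean of every array lay between 500.04 and 500.05, so the deposited intensity values were used without further scaling. Detection calls and scanner files were not used here, so it could not be judged which probe sets lay above background, and low signals are the least certain. The number of arrays limits the precision.

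Of 22810 probe sets, 64 controls were set aside. Values were taken to log2(signal + 7.56), where 7.56 was the 10th percentile of all values, and a fold change on this scale understates the change of dim probe sets. The 15922 probe sets whose mean over all arrays lay above the 30th percentile were tested. One limma fit (version 3.58.1, R 4.3.3; lmFit and eBayes with a trended prior) held all 23 arrays as 9 group means, so that all groups shared 1 estimate of the spread, with 14 residual degrees of freedom. The shared estimate assumes an equal spread in all groups. The third 1 µM IAA array had a limma quality weight, lower for noisier arrays, of 0.0608, against 0.409 or more on the others. P-values may thus be too small for contrasts with the 1 µM IAA group and too large for others. Counts with only the groups of each contrast are therefore also given. Each treatment was set against the mock with the same replicate numbers. P-values were adjusted by Benjamini-Hochberg within each of 14 contrasts, and a probe set was called at an adjusted p below 0.05. All adjusted p-values for genes are from this limma fit.

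Gene names came from the platform annotation, updated through gene identifiers to the TAIR10.1 gene table, which was used for names only. Of all probe sets, 13513 had 1 gene, 503 had several and 8794 were unnamed here; 13436 matched the gene table. Many genes carry only a locus code in that table. A gene with several probe sets was represented by the one with the highest mean.

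The tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. For IAA at 1 µM, kynurenine, PEO-IAA and PPBo against mock, the rule takes the 6 called probe sets with the highest and the 6 with the lowest log2 fold change among those naming 1 gene, with no overlap between treated and mock arrays and a mean of the higher group above the median of tested probe sets. It takes 3 of each for the other contrasts. The overlap and level conditions were not applied to differences between 2 responses. From each list it adds up to 4 called members with the smallest p, members not called may be named with values, and any member of the early auxin-induced core may be named. Genes that are called up with 1 µM IAA and down with all 3 inhibitors, or the reverse, may be named up to a number of 8. Outside the rule, AT1G64405, AT4G31470 and AT4G30460 were named as opposite calls with PEO-IAA after their values were seen.

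Of 370 different loci in the 23 lists, 46 had a probe set naming 1 gene and 36 were tested, so most list members were not measured under a name here. In 8 of the 23 lists no member was tested (SAUR family, auxin receptors and response factors, ethylene, gibberellin and brassinosteroid metabolism, jasmonate, boron transport, mitotic cell cycle and root tissue markers). Lists were tested with limma's fry (directional, trended prior, Benjamini-Hochberg over the lists of a contrast), with camera and an estimated correlation as the alternative. Fry's directional p asks whether a list's genes move, on balance, one way, and compares the list with no other genes. GH3.3 and GH3.5 belong both to the core and to the auxin conjugation and oxidation list, and IAA29 both to the core and to the Aux/IAA list. Results of these lists are therefore not independent of each other. A further 7 families, picked by symbol after the annotation but before any fold change was seen, were adjusted apart. A list of 73 class III peroxidase loci was added after fold changes had been seen; the gene table names 14 of them as peroxidases, and the others were listed from general knowledge.

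Chance overlap and correlation between contrasts that share a mock were simulated 50 times from unchanged, independent groups, and correlation again, a test chosen after seeing the data, with mock, kynurenine and both PEO-IAA groups paired by replicate number at r = 0.51, the mean of the values given for these groups against mock. Data were also simulated with each probe set's mean over all arrays and its shared spread, with independent arrays of equal quality. There 77% of 2-fold and 98% of 4-fold changes were recovered for 1 µM IAA against mock, and 63% and 96% for PPBo against mock. Each share is of 100 changed probe sets among 15922 tested, in a single simulated data set per contrast. These data held neither the pairing nor an array like the third 1 µM IAA array, so the shares may not hold for the real arrays.

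Same-numbered arrays deviated together from their group means in mock and kynurenine (r = 0.63, 0.48 and 0.43 across probe sets), mock and PEO-IAA (0.55, 0.41 and 0.41), mock and PEO-IAA plus IAA (0.63, 0.57 and 0.49) and PEO-IAA with and without IAA (0.55, 0.35 and 0.44). For these contrasts the numbers were taken to pair the arrays, from this check and not from the labels. The 1 µM IAA arrays did not pair with mock (0.04, -0.13 and -0.05), and replicates 4 and 5 give too few pairs to judge. A block shared by all groups therefore does not describe the 1 µM IAA group. Calls and counts from the block in contrasts with that group are given for completeness and are not relied on. With the replicate number as a block, the called probe sets numbered 148 for PEO-IAA against mock (104 without the block), 252 for PEO-IAA plus IAA against mock (170), 265 for PEO-IAA plus IAA against PEO-IAA (206) and 1 for kynurenine against mock (1).

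Alternatives were other pseudocounts, median centring and quantile normalization, no filter and a stricter filter, other variance models, fewer arrays in the fit, a replicate block, all 5 mock arrays as 1 control, a 2-fold minimum, and leaving out each array. Chosen after seeing the data were array quality weights, leaving out the third 1 µM IAA array from every contrast, and that together with the replicate block.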

Results

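The series measured transcripts in Arabidopsis seedlings after 3 h with auxin, with compounds that lower auxin synthesis or action, or with both. By its title, it sought genes that respond to auxin by using auxin inhibitors. Kynurenine inhibits TAA1, which makes indole-3-pyruvate from tryptophan. PPBo inhibits the YUCCA enzymes that turn indole-3-pyruvate into IAA. PEO-IAA, a derivative of IAA, blocks the TIR1/AFB auxin receptors. Groups held 3 arrays each for replicates 1 to 3 and 2 arrays each for replicates 4 and 5. Signals are means ± SD of the MAS5 intensity, and changes are log2 fold changes ± SE.

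The third 1 µM IAA array stood apart from the others. Its median correlation with the other arrays, across probe sets, was 0.881, against 0.951 to 0.969 for the other 22 arrays. Its 3′ to 5′ GAPDH signal ratio, a measure of RNA integrity, was 24.4, against 1.19 to 2.05. The reference genes did not pass the test with 1 µM IAA, with TIP41 (AT4G34270) at 0.11 ± 0.15 and SAND (AT2G28390) at -0.11 ± 0.14.

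With 1 µM IAA, genes known as early auxin targets rose strongly. GH3.3 (AT2G23170), which conjugates IAA to amino acids, went from a signal of 317 ± 124 in mock (n = 3) to 13945 ± 1272 (n = 3), a log2 change of 5.50 ± 0.42. LBD29 (AT3G58190), a LOB-domain factor of lateral root formation, rose by 4.20 ± 0.46, and IAA29 (AT4G32280), an Aux/IAA repressor, by 3.25 ± 0.25. GH3.5 (AT4G27260) rose by 2.56 ± 0.27, AT5G62280 by 2.44 ± 0.28 and HAT2 (AT5G47370), a homeodomain-leucine zipper factor, by 2.40 ± 0.18. AT3G01190, a class III peroxidase, fell from 1286 ± 606 to 175 ± 106, a log2 change of -2.87 ± 0.33.

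All 6 tested members of the early auxin-induced core rose with 1 µM IAA, LBD16 (AT2G42430) least at 1.35 ± 0.33 and with a call that ended whichever array was left out, and adjusted over the list alone the count was also 6 (fry adjusted p = 5.84e-10). Of 6 auxin conjugation and oxidation genes, GH3.3 and GH3.5 rose and 4 did not pass, with 2 also adjusted over the list alone (list adjusted p = 4.07e-06). Those not passing were GH3.17 at 0.50 ± 0.29, DAO1 at 0.17 ± 0.19, GH3.9 at -0.13 ± 0.22 and DAO2 at -0.87 ± 0.40. Of the Aux/IAA genes tested, IAA29 rose and IAA18 was at 0.06 ± 0.19 (list adjusted p = 2.26e-06). At the stricter filter IAA29 was not tested in any contrast, so the list there was IAA18 alone (list adjusted p = 0.992). Among 8 genes of cell wall loosening the expansin EXPA8 (AT2G40610) rose by 1.30 ± 0.23 and 7 did not pass, such as XTH19 at 0.53 ± 0.16 and EXPA15 at -0.50 ± 0.13 (list adjusted p = 0.683, with a mean of 0.11 and a median of -0.12), and adjusted over the list alone 2 were up and 1 down. The root hair expansins EXPA7 and EXPA18 were at -0.35 ± 0.39 and -0.61 ± 0.23, and the list did not pass (adjusted p = 0.320). Single tested members of other lists did not pass, with the biosynthesis gene YUC2 at 0.17 ± 0.17, the kinase WAG2, an auxin transport regulator, at 0.20 ± 0.29 and the cytokinin response regulator ARR16 at -0.26 ± 0.21. The tryptophan pathway gene IGPS was at -0.76 ± 0.29 and the glucosinolate gene UGT74B1 at -0.46 ± 0.20, both uncalled over all genes, and the list did not pass (adjusted p = 0.107), although adjusted over the list alone both passed, as lower.

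Lower with 1 µM IAA were also the peroxidases AT4G30170 (-1.88 ± 0.13) and AT4G11290 (-1.58 ± 0.15), as well as AT3G62040 (-1.63 ± 0.31), AT4G30450 (-1.43 ± 0.16) and AT2G41800 (-1.35 ± 0.25). The glycosyltransferases UGT71C1 (AT2G29750) and UGT71C3 (AT1G07260) fell by 2.44 and 0.91, and the tau-class glutathione transferases GSTU28 (AT1G53680) and GSTU26 (AT1G17190) fell by 1.55 and 1.07. In all, 337 probe sets were called, 145 up and 192 down, and 143 of them named 1 gene. Without the third IAA array 347 were called and 242 of these calls were shared, while the count was 196 without mock replicate 1, 206 without mock replicate 2 and 821 without the first IAA array. Of 21 named calls 16 held whichever array was left out, and the calls of LBD16, GSTU28 and GSTU26 did not. LBD16 lost its call in 6 of 6 such fits (adjusted p up to 0.139), without a filter (0.0531), with a pseudocount of 1.89 (0.0517), with the arrays of replicates 1 to 3 alone (0.0984) and with mock and IAA alone (0.0547), and GSTU28 (0.0627) and GSTU26 (0.0552) lost theirs in 1, without mock replicate 2. With mock and IAA alone 55 probe sets were called and 11 of the 21 named calls held, and among those that ended were UGT71C1 (0.383), GSTU26 (0.190), GSTU28 (0.138), AT3G62040 (0.131), UGT71C3 (0.0984), AT3G01190 (0.0654) and EXPA8 (0.0567).

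**Figure D1:**
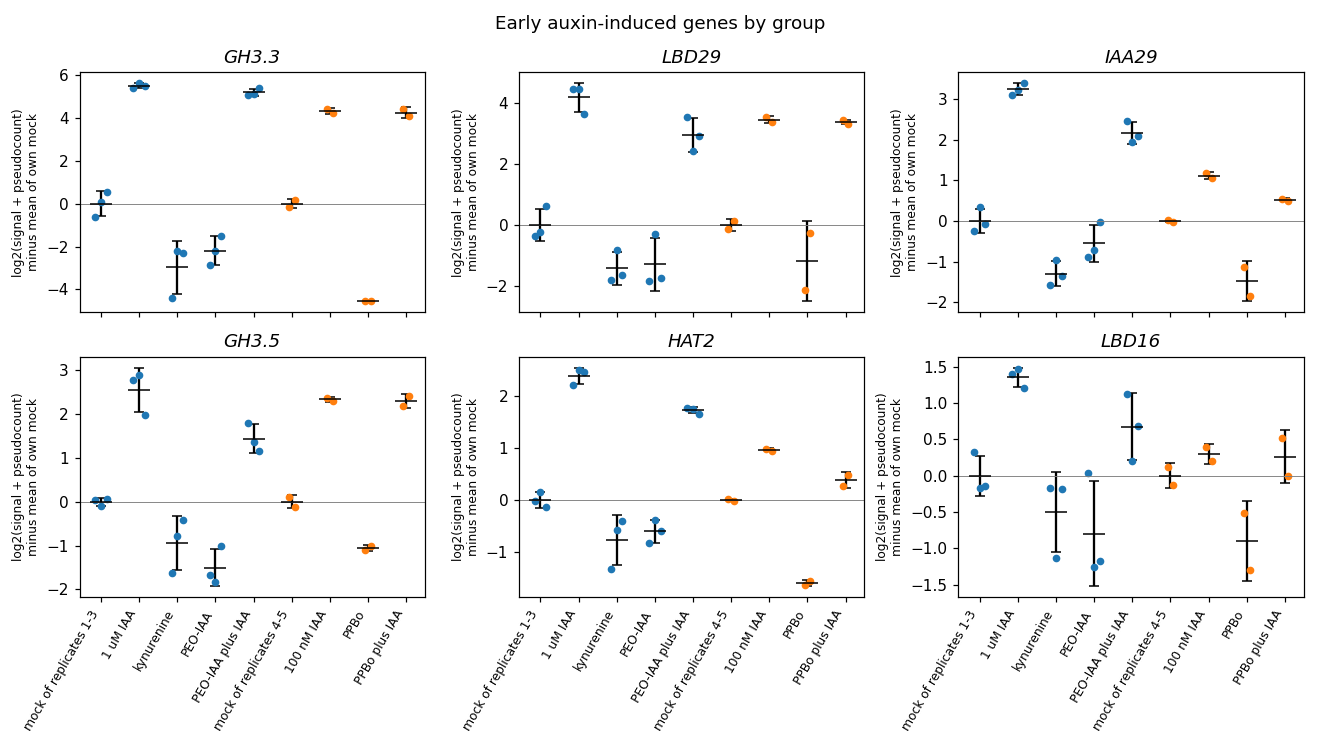
Levels of 6 early auxin-induced genes, as log2(signal + pseudocount) minus the mean of the mock with the same replicate numbers, by treatment group. Points are arrays, bars are the mean and SD, and blue and orange mark replicates 1 to 3 and 4 to 5; the mean of GH3.3 was at 5.50 with 1 µM IAA and at -4.56 with PPBo.

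Kynurenine tested what lowering auxin synthesis at TAA1 changes. GH3.3 fell from 317 ± 124 in mock (n = 3) to 40.2 ± 28.6 (n = 3), a log2 change of -2.97 ± 0.42, and was the one called probe set. The early auxin-induced core fell as a list (fry adjusted p = 6.38e-05), with all 6 genes lower and 5 called adjusted over the list alone. Besides GH3.3 its members were LBD29 at -1.43 ± 0.46, IAA29 at -1.30 ± 0.25, GH3.5 at -0.94 ± 0.27, HAT2 at -0.77 ± 0.18 and LBD16 at -0.50 ± 0.33. IAA29 was called in 1 of 21 alternatives, with array quality weights (0.0263).

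The Aux/IAA list, of 2 tested genes, passed with kynurenine (list adjusted p = 0.0180) through IAA29, which was uncalled over all genes, with IAA18 at -0.01 ± 0.19. It did not pass without a filter (0.125), with the arrays of replicates 1 to 3 alone (0.139), with mock and kynurenine alone (0.108) or without the first kynurenine array (0.0706). At the stricter filter, where IAA18 alone was left in it, the list was at 0.981. The auxin conjugation and oxidation list fell by its test (adjusted p = 0.0180) although its median was 0.02 and its mean -0.60, since GH3.17 was at 0.10 ± 0.29, DAO1 at 0.03 ± 0.19 and DAO2 at 0.16 ± 0.40. Its call ended without mock replicate 3 (0.0587), with the arrays of replicates 1 to 3 alone (0.128) and with mock and kynurenine alone (0.572). WAG2 was at -0.73 ± 0.29. The detoxification genes GSTU22, GSTU25 and UGT73B4 were at 0.01 ± 0.23, 0.13 ± 0.49 and -0.10 ± 0.31. All 8 genes of cell wall loosening were lower without passing (list adjusted p = 0.322), such as EXPA15 at -0.27 ± 0.13. At an unadjusted p under 0.05 there were 302 probe sets, against 796.1 from chance, and 368 with mock and kynurenine alone. Fewer than from chance means that the test was too strict here, so the low count is no evidence that little changed. The main fit did not use the pairing of these arrays, though the replicate block also called 1 probe set. The GH3.3 call ended without mock replicate 2 (adjusted p = 0.163), without mock replicate 3 (0.265), with a pseudocount of 1.89 (0.0510), with the arrays of replicates 1 to 3 alone (0.321) and with mock and kynurenine alone (0.9998), and the core list ended in the last of these (0.0793).

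PEO-IAA tested what blocking auxin perception changes. Genes of detoxification rose, among them the tau-class glutathione transferase GSTU22 (AT1G78340), which went from 313 ± 18.3 in mock (n = 3) to 1575 ± 445 (n = 3), a log2 change of 2.26 ± 0.23. GSTU25 (AT1G17180) rose by 2.85 ± 0.49 and the glycosyltransferase UGT73B4 (AT2G15490) by 2.68 ± 0.31. The root hair expansins EXPA7 (AT1G12560) and EXPA18 (AT1G62980) changed by -2.11 ± 0.39 and -1.71 ± 0.23, and GH3.3 and GH3.5 by -2.19 ± 0.42 and -1.50 ± 0.27.

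All 3 tested detoxification genes rose with PEO-IAA, also adjusted over the list alone (fry adjusted p = 6.21e-06), and both root hair genes fell (0.000103). The early auxin-induced core fell (0.000103), with 2 of 6 called and 6 adjusted over the list alone, and the others were LBD29 at -1.30 ± 0.46, LBD16 at -0.80 ± 0.33, HAT2 at -0.60 ± 0.18 and IAA29 at -0.55 ± 0.25. HAT2 was called in 3 of 22 alternatives, with mock replicates 1 to 5 as 1 control (0.0305), with array quality weights (0.0392) and with the replicate block without the third IAA array (0.0454). Cell wall loosening fell (adjusted p = 0.000715), with EXPA15 (AT2G03090) called at -0.93 ± 0.13 and 3 of 8 called adjusted over the list alone. EXPA4 was at -0.71 ± 0.21 and XTH19 at -0.49 ± 0.16, and the list did not pass with mock and PEO-IAA alone (0.0819). With mock replicates 1 to 5 as 1 control EXPA15 was at -0.68 and uncalled (0.0538). Auxin conjugation and oxidation fell (0.0287), a call lost in 8 of 22 alternatives, among them an estimated correlation (adjusted p = 0.0746 with an estimated correlation) and leaving out mock replicate 3 (0.118), with GH3.3 and GH3.5 down, DAO1 at 0.57 ± 0.19, and 2 down and 1 up adjusted over the list alone. The one tested auxin transport gene, WAG2, passed as a list of 1 at -0.98 ± 0.29 (list adjusted p = 0.0237) and was not called over all genes. The Aux/IAA list did not pass (0.118).

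Other genes called with PEO-IAA were AT2G32020 (3.13 ± 0.37), AT2G41730 (2.54 ± 0.48), AT5G14730 (1.89 ± 0.24) and UGT73B5 (AT2G15480, 1.47 ± 0.21), all up. Down were the peroxidases AT3G49960 (-4.03 ± 0.61) and AT1G30870 (-2.24 ± 0.31), AT3G25930 (-2.33 ± 0.27), AT2G30660 (-1.12 ± 0.24) and AT1G03820 (-0.88 ± 0.19). In all 104 probe sets were called, 57 up and 47 down, and 159 without the third 1 µM IAA array, which is not in this contrast but enters the shared spread. The count was 64 without mock replicate 2 and 67 without the third PEO-IAA array, and of 17 named calls 11 held whichever array was left out; GH3.3 (adjusted p up to 0.0964, lost in 4 of 7 such fits), EXPA7 (0.0614, in 2) and GH3.5 (0.0630, without the second PEO-IAA array) were among the 6 that did not, as were AT1G03820 (up to 0.248, in 5), AT2G30660 (0.237, in 4) and AT2G41730 (0.100, in 4). With mock and PEO-IAA alone 10 of the 17 held, and GSTU25 (0.0970), AT1G30870 (0.0743), EXPA7 (0.201) and GH3.3 (0.0760) were among the 7 that ended. With mock replicates 1 to 5 as 1 control AT2G30660 was at -0.75 (0.356) and AT1G03820 at -0.74 (0.0569), both uncalled.

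**Figure D2:**
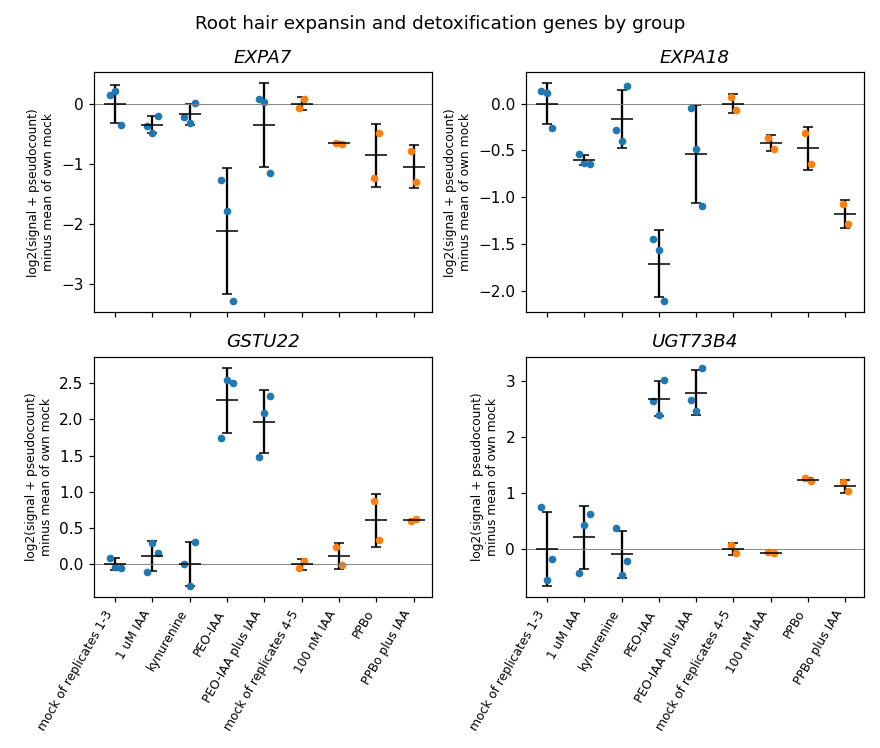
Levels of the root hair expansins EXPA7 and EXPA18 and of GSTU22 and UGT73B4, as log2(signal + pseudocount) minus the mean of the mock with the same replicate numbers, by treatment group. Points are arrays, bars are the mean and SD, and blue and orange mark replicates 1 to 3 and 4 to 5; with PEO-IAA the mean of EXPA18 was at -1.71 and that of GSTU22 at 2.26.

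PEO-IAA plus IAA showed whether IAA still acted beside PEO-IAA. Against PEO-IAA alone, GH3.3 went from 64.8 ± 33.2 (n = 3) to 11310.2 ± 1388 (n = 3), a log2 change of 7.39 ± 0.42. LBD29 rose by 4.27 ± 0.46, GH3.5 by 2.95 ± 0.27, AT5G62280 by 2.72 ± 0.28, IAA29 by 2.71 ± 0.25 and HAT2 by 2.34 ± 0.18. The root hair expansins EXPA7 and EXPA18 rose by 1.76 ± 0.39 and 1.17 ± 0.23. AT5G60520 (-2.36 ± 0.21), AT4G11190 (-1.93 ± 0.39) and AT3G45680 (-1.58 ± 0.24) fell.

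All 6 core genes rose on adding IAA to PEO-IAA (fry adjusted p = 2.62e-10), LBD16 by 1.47 ± 0.33, with 6 also adjusted over the list alone. The auxin conjugation and oxidation list and the Aux/IAA list rose (both adjusted p = 7.27e-07). Their called genes, GH3.3 and GH3.5 in the first and IAA29 in the second, are also core members. Both root hair genes rose as well (0.00101), as did cell wall loosening (0.0127), where EXPA8 was called at 1.02 ± 0.23 and 3 of 8 were called adjusted over the list alone. The cell wall list did not pass without the first or second PEO-IAA plus IAA array (0.0648 and 0.0534), nor did it (0.0574) or the root hair list (0.135) with the PEO-IAA arrays with and without IAA alone. The Aux/IAA list did not pass at the stricter filter, where it held IAA18 but not IAA29 (0.195). In all 206 probe sets were called, 101 up and 105 down, and 333 without the third 1 µM IAA array, with 111, 134 and 128 without the first or second PEO-IAA array or the second PEO-IAA plus IAA array. Of 18 named calls 9 held whichever array was left out, and LBD16 (adjusted p up to 0.186, lost in 4 of 7 such fits), EXPA7 (0.152, in 3), EXPA8 (0.157, in 5) and EXPA18 (0.0624, in 2) did not. With the PEO-IAA arrays with and without IAA alone 10 of the 18 held, and these 4 were among the 8 that ended.

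Against mock, PEO-IAA plus IAA raised both auxin-induced genes and the 3 tested members of the detoxification list. GH3.3 rose by 5.19 ± 0.42, LBD29 by 2.97 ± 0.46, IAA29 by 2.16 ± 0.25, HAT2 by 1.73 ± 0.18 and GH3.5 by 1.44 ± 0.27, while LBD16 was at 0.67 ± 0.33. UGT73B4 rose by 2.78 ± 0.31, GSTU25 by 2.50 ± 0.49 and GSTU22 by 1.96 ± 0.23, and EXPA8 by 1.10 ± 0.23. AT4G15390 (-1.64 ± 0.24), AT3G62040 (-1.45 ± 0.31), AT2G30660 (-1.31 ± 0.24) and EXPA15 (-0.91 ± 0.13) fell. The core list (5 of 6 up, also 5 adjusted over the list alone) and the detoxification list (3 of 3) rose, at adjusted p = 4.78e-08 and 7.24e-06. In all 170 probe sets were called, 78 up and 92 down, and 293 without the third 1 µM IAA array, 113 and 72 without mock replicate 1 or 2 and 64 without the third PEO-IAA plus IAA array. Of 20 named calls 11 held whichever array was left out, and GSTU25 (adjusted p up to 0.107) and AT3G62040 (0.168, both without the third PEO-IAA plus IAA array), EXPA8 (0.104) and GH3.5 (0.0619, both without mock replicate 2) were among those that did not. With mock and PEO-IAA plus IAA alone 8 of the 20 held, and GSTU25 (0.193), AT3G62040 (0.236), EXPA8 (0.140), EXPA15 (0.0621) and AT4G15390 (0.0620) were among the 12 that ended.

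Against 1 µM IAA, adding PEO-IAA lowered the early auxin-induced core as a list (fry adjusted p = 0.00137), with no gene called over all genes and 4 adjusted over the list alone. Its values were LBD29 at -1.23 ± 0.46, GH3.5 at -1.11 ± 0.27, IAA29 at -1.08 ± 0.25, LBD16 at -0.68 ± 0.33, HAT2 at -0.66 ± 0.18 and GH3.3 at -0.30 ± 0.42. GH3.5 was called in 3 of 20 alternatives, without the third IAA array (-1.40, adjusted p = 0.0264), with the block as well (0.00567) and with array quality weights (0.00117), and IAA29 in 2 of 19. The detoxification genes rose (3 of 3, adjusted p = 1.90e-05), with GSTU25 at 2.84 ± 0.49, UGT73B4 at 2.57 ± 0.31 and GSTU22 at 1.85 ± 0.23. The peroxidase AT3G01190 rose by 2.25 ± 0.33, and AT1G30760 (-2.23 ± 0.39), AT1G64405 (-1.47 ± 0.30) and AT1G67750 (-1.04 ± 0.18) fell. In all 58 probe sets were called, 40 up and 18 down, and 59 without the third IAA array with 41 calls shared, 102 without the first IAA array and 28 without the third PEO-IAA plus IAA array. Of 10 named calls 5 held whichever array was left out. Without the third PEO-IAA plus IAA array the calls of GSTU25 (adjusted p = 0.0757), AT1G30760 (0.0674), AT1G64405 (0.225, lost in 5 of 6 such fits) and AT1G67750 (0.0662) ended, and the core list ended at the stricter filter (0.0565). With IAA and PEO-IAA plus IAA alone limma called 0 probe sets, with 503 at an unadjusted p under 0.05, and all 10 named calls ended (UGT73B4 and GSTU22 at 0.229, GSTU25 at 0.302, AT3G01190 at 0.361 and AT1G30760 at 0.443).

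Whether IAA changed genes by a different amount beside PEO-IAA than alone was tested as an interaction. No core gene was called, with IAA29 at -0.54, GH3.3 at 1.89 and the core list at an adjusted p of 0.826. The root hair list had a more positive response beside PEO-IAA (adjusted p = 0.00538), with EXPA18 called at 1.78 ± 0.32 and EXPA7 at 2.11, and both called adjusted over the list alone, and the list did not pass with these 4 groups alone (0.0826). AT3G25930 (3.27 ± 0.38), AT5G04960 (2.72 ± 0.43) and the peroxidases AT1G30870 (2.62 ± 0.44) and AT4G30170 (1.32 ± 0.19) were also called. In all 16 probe sets were called, 13 up and 3 down, and 16 without the third IAA array with 12 shared. The count was 9 or 10 without mock replicate 1 or 2, the second IAA array, PEO-IAA replicate 2 or 3 or PEO-IAA plus IAA replicate 1 or 2, and the calls of EXPA18 (adjusted p up to 0.123) and AT1G30870 (0.0820) ended in 8 and 6 of 12 such fits. With these 4 groups alone 1 probe set was called and all 5 named calls ended, AT3G25930 at 0.0565.

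PEO-IAA and IAA are related compounds and were compared directly, at different doses of 10 and 1 µM. All 6 core genes were lower with PEO-IAA (fry adjusted p = 1.04e-11), GH3.3 by -7.69 ± 0.42, LBD29 by -5.50 ± 0.46, GH3.5 by -4.06 ± 0.27, IAA29 by -3.79 ± 0.25 and LBD16 by -2.15 ± 0.33. AT3G01190 (3.68 ± 0.33), AT2G32020 (3.22 ± 0.37), GSTU25 (3.18 ± 0.49) and DAO2, which oxidises IAA (1.55 ± 0.40), were higher. WAG2 (-1.18 ± 0.29), EXPA4 (-1.21 ± 0.21) and XTH19 (-1.01 ± 0.16) were lower. Detoxification was higher (adjusted p = 2.01e-06) and cell wall loosening (0.000135) and root hair formation (0.000882) were lower. In all 630 probe sets were called, 365 up and 265 down, and 609 without the third IAA array with 474 shared, 1083 and 955 without the first or second IAA array and 391 without the first PEO-IAA array. Of 27 named calls 24 held whichever array was left out. Without the first PEO-IAA array the calls of DAO2 (adjusted p = 0.230, lost in 4 of 6 such fits) and WAG2 (0.140) ended, and with IAA and PEO-IAA alone 16 of the 27 held, and DAO2 (0.355), WAG2 (0.390), EXPA4 (0.131) and XTH19 (0.0762) were among the 11 that ended.

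With 100 nM IAA, 3 of the 6 core genes rose. GH3.3 went from 429 ± 62.9 in mock (n = 2) to 8613 ± 827 (n = 2), a log2 change of 4.31 ± 0.52, LBD29 rose by 3.46 ± 0.56, PR-1-LIKE (AT2G19990) by 2.41 ± 0.51 and GH3.5 by 2.34 ± 0.34. The peroxidases AT3G01190 (-2.81 ± 0.41), AT4G30170 (-1.32 ± 0.16) and AT4G11290 (-1.19 ± 0.19) fell, as did AT1G30990 (-1.67 ± 0.23) and AT1G54890 (-1.33 ± 0.23).

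The core rose with 100 nM IAA (fry adjusted p = 5.47e-06), with 3 of 6 called and 5 adjusted over the list alone, and IAA29 was at 1.12 ± 0.30, HAT2 at 0.97 ± 0.22 and LBD16 at 0.30 ± 0.41. HAT2 was called in 7 of 20 alternatives, such as with the arrays of replicates 4 and 5 alone (0.000970) and with the replicate block (0.0325), and IAA29 in 3 of 19. The conjugation and oxidation list rose (adjusted p = 0.000504), and its called genes, GH3.3 and GH3.5, are also core members. The Aux/IAA list passed (0.0168) with no gene called over all genes, and did not without a filter (0.0548) or with mock and IAA alone (0.0681). At the stricter filter, where it held IAA18 but not IAA29, it was at 0.969. Nor did it pass without mock replicate 4 or 5 or without IAA replicate 4, fits that leave 1 array in a group. EXPA8 was at 0.90 ± 0.28 and EXPA15 at -0.58 ± 0.16, both uncalled. In all 51 probe sets were called, 28 up and 23 down, and 71 without the third 1 µM IAA array, 19 and 12 without mock replicate 4 or 5 and 16 and 25 without IAA replicate 4 or 5. Of 10 named calls, GH3.3 and AT4G30170 held whichever array was left out, LBD29 had an adjusted p up to 0.105 (without IAA replicate 4), and PR-1-LIKE (up to 0.592), AT3G01190 and GH3.5 (both 0.0506) lost theirs without mock replicate 5.

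The response to 1 µM IAA was set against that to 100 nM, each relative to its own mock. The core list responded more at 1 µM (fry adjusted p = 0.00754), with 2 of 6 called adjusted over the list alone, and the values were IAA29 at 2.13 ± 0.39, HAT2 at 1.43 ± 0.28, GH3.3 at 1.19 ± 0.67, LBD16 at 1.06 ± 0.53, LBD29 at 0.74 ± 0.73 and GH3.5 at 0.22 ± 0.43. IAA29 was called in 2 of 22 alternatives and HAT2 in 2 of 23. The Aux/IAA list passed (0.0407) and did not in 13 of 23 alternatives, such as with an estimated correlation (adjusted p = 0.0703 with an estimated correlation). Over all genes limma called 0 probe sets, with 448 at an unadjusted p under 0.05. This is below the 796.1 from chance, so the test was strict here and does not show equal responses. Across probe sets, which are not independent replicates, the log2 changes at both doses had r = 0.50, against 0.00 in simulated unchanged data, and 45 probe sets were called the same way at both doses, 26 up and 19 down. The doses were measured on different replicate sets, and the core list lost its call without the fifth 100 nM array (adjusted p = 0.0550) and at the stricter filter (0.246).

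PPBo tested what lowering auxin synthesis at YUCCA changes. GH3.3 fell from 429 ± 62.9 in mock (n = 2) to 10.9 ± 0.0449 (n = 2), a log2 change of -4.56 ± 0.52. HAT2 fell by 1.60, EXPA8 by 1.59 and IAA29 by 1.48. AT1G19020 (1.99 ± 0.33), AT1G05340 (1.72 ± 0.29), AT5G01740 (1.22 ± 0.22) and AT3G26470 (1.10 ± 0.22) rose.

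The core fell with PPBo (fry adjusted p = 1.25e-05), with 3 of 6 called and 6 adjusted over the list alone, and the others were LBD29 at -1.20 ± 0.56, GH3.5 at -1.06 ± 0.34, called in 3 of 20 alternatives, and LBD16 at -0.90 ± 0.41. Cell wall loosening fell (0.000264), all 8 genes being lower, with EXPA8 and EXPA15 (-0.77 ± 0.16) called, 5 called adjusted over the list alone, and XTH19 at -0.82 ± 0.19, EXPA4 at -0.95 ± 0.26 and XTH33 at -0.94 ± 0.32. Conjugation and oxidation fell (0.00288), with GH3.3, also a core member, as its called gene. The Aux/IAA list did not pass (0.0626), nor did detoxification (0.251), with UGT73B4 at 1.24 ± 0.38 and GSTU22 at 0.60 ± 0.28, nor root hair formation (0.251), with EXPA7 at -0.86 ± 0.48. AT5G50335 (-1.97 ± 0.37), AT4G14390 (-1.02 ± 0.21) and AT3G45620 (-0.73 ± 0.13) fell, calls that ended in 4, 3 and 4 of 5 fits with 1 array left out. With mock replicates 1 to 5 as 1 control AT5G50335 was at -1.12 (adjusted p = 0.270) and AT3G26470 at 0.71 (0.173), both uncalled.

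With PPBo 57 probe sets were called, 17 up and 40 down, and 114 without the third 1 µM IAA array, 18 and 10 without mock replicate 4 or 5 and 23 and 16 without PPBo replicate 4 or 5. Of 12 named calls, GH3.3 and HAT2 held whichever array was left out, and among the others the adjusted p reached 0.445 for IAA29 and 0.244 for EXPA8 without PPBo replicate 5, and 0.153 for AT1G19020 and 0.565 for EXPA15 without mock replicate 5.

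PPBo plus IAA raised GH3.3, LBD29 and GH3.5, both against PPBo and against mock. Against PPBo alone GH3.3 rose by 8.80 ± 0.52, LBD29 by 4.58 ± 0.56, GH3.5 by 3.37 ± 0.34, IAA29 by 2.01 ± 0.30, HAT2 by 1.99 ± 0.22 and EXPA8 by 1.24 ± 0.28, LBD16 was at 1.16 ± 0.41, and AT3G01190 (-2.50 ± 0.41), AT1G05340 (-1.35 ± 0.29) and AT1G29020 (-1.06 ± 0.21) fell. Against mock GH3.3 rose by 4.24 ± 0.52, LBD29 by 3.39 ± 0.56 and GH3.5 by 2.31 ± 0.34, while IAA29 was at 0.53 ± 0.30, HAT2 at 0.38 ± 0.22 and LBD16 at 0.26 ± 0.41. AT3G01190 (-2.92 ± 0.41), GSTU28 (-2.22 ± 0.39), AT5G41280 (-2.08 ± 0.29), AT1G14960 (-2.04 ± 0.34), GSTU26 (-1.47 ± 0.25), EXPA18 (-1.18 ± 0.28) and EXPA15 (-1.02 ± 0.16) fell against mock. The core list rose in both (fry adjusted p = 4.18e-09 against PPBo, with 5 of 6 called, and 5.92e-05 against mock, with 3 of 6), with 6 and 3 adjusted over the list alone. Against mock cell wall loosening fell (0.00649), a call that ended without mock replicate 5 (0.0581). Root hair formation passed as lower (0.0239) and did not without mock replicate 4 or 5 (0.105 and 0.0949), without PPBo plus IAA replicate 5 (0.190) or with mock replicates 1 to 5 as 1 control (0.0891).

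Against PPBo 96 probe sets were called, 66 up and 30 down, with 48, 54, 56 and 58 without PPBo replicate 4 or 5 or PPBo plus IAA replicate 4 or 5, and against mock 157 were called, 60 up and 97 down, with 261 without the third 1 µM IAA array, 80 and 62 without mock replicate 4 or 5 and 59 and 72 without PPBo plus IAA replicate 4 or 5. Against PPBo 6 of 14 named calls held whichever array was left out, and those that did not include EXPA8 (adjusted p up to 0.757, lost in 3 of 5 such fits), AT1G05340 (0.469, in 4, and 0.0539 without a filter), AT1G29020 (0.451, in 3) and AT3G01190 (0.0691, in 2). Against mock 7 of 16 held, and those that did not include EXPA18 (0.435, in 4), GSTU28 (0.156, in 2), GSTU26 (0.0633, in 2), EXPA15 (0.0589, in 1), AT1G14960 (0.0534, in 1) and LBD29 (0.0508, in 1).

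Genes moved oppositely by auxin and by an inhibitor were counted. GH3.3 was the one gene up with 1 µM IAA and down with all 3 inhibitors. With PEO-IAA 13 probe sets were up with IAA and down with the inhibitor and 3 the reverse, against 0.428 and 0.687 from chance overlap, and 3 were up and 9 down in both. Named among them were GH3.3, GH3.5, AT1G64405 (-1.43 ± 0.30 with PEO-IAA) and AT1G03820 (1.11 with IAA and -0.88 with PEO-IAA), and for the reverse AT4G31470 (-1.46 and 1.67) and AT4G30460 (-1.46 and 0.91); AT1G64405, AT4G31470 and AT4G30460 were chosen for this after their values were seen. With PPBo 18 were up with IAA and down with the inhibitor and 0 the reverse in limma's calls (chance 0.364 and 0.205), among them GH3.3, IAA29, HAT2 and EXPA8. With kynurenine the count was 1, GH3.3, and it was 0 without mock replicate 2 or 3. Without any 1 of mock replicates 1 to 3 the PEO-IAA count was 6 in place of 16, and it was 9 and 10 without PEO-IAA replicate 2 or 3; the PPBo count was 33 without the third IAA array, 6 and 5 without mock replicate 4 or 5 and 7 without PPBo replicate 5. The count for all 3 was 0 without mock replicate 2 or 3 or the first or second PEO-IAA array.

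Responses were also compared across probe sets, which are not independent replicates. Contrasts sharing a mock had r = 0.50 in unchanged data simulated from independent groups, and 0.35 for 1 µM IAA with kynurenine or PEO-IAA when the pairing of these with mock was simulated. The observed r was 0.05 for 1 µM IAA and kynurenine, 0.15 for 1 µM IAA and PEO-IAA, 0.47 for kynurenine and PEO-IAA and 0.15 for PPBo and 100 nM IAA. Between sets with separate mocks r was 0.31 for PEO-IAA and PPBo, 0.21 for kynurenine and PPBo, 0.01 for 1 µM IAA and PPBo, -0.11 for kynurenine and 100 nM IAA and -0.01 for PEO-IAA and 100 nM IAA, against 0.00 simulated. The responses to IAA added to PEO-IAA and to PPBo, a pair chosen after seeing the data, had r = 0.53, with 56 probe sets called the same way and 1 oppositely.

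PPBo and kynurenine, which act at successive steps of auxin synthesis, were compared through their responses, at doses of 10 and 30 µM. They were measured on different replicate sets, so a difference between the inhibitors cannot be told apart from one between the sets. GH3.3 was at -1.59 ± 0.67 and HAT2 at -0.84 ± 0.28, both uncalled, and the core list did not differ by its test (fry adjusted p = 0.660). Cell wall loosening was lower with PPBo (0.0464), with no gene called and 2 adjusted over the list alone. The 4 called probe sets, with log2 differences of -2.95, -2.84, -2.57 and 2.41, were unnamed here. At an unadjusted p under 0.05 limma gave 494 probe sets, below the 796.1 from chance. The test was thus strict here and does not show equal responses. The count was 7 without the third 1 µM IAA array, and the cell wall list ended without mock replicate 2 to 5 or other single arrays, with an adjusted p up to 0.213, and after quantile normalization (0.0606) or median centring (0.0660).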

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

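The tests chosen only after the result was seen are the GAPDH ratio and the auxin gene level for the third IAA array, the response of detoxification genes to added IAA, the arrays and residual SD of the random splits, the correlations over 8 groups for the third IAA array, and both tests of the PPBo plus IAA arrays.

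Several values stood out because a response differed between groups by the interaction test. The response to IAA differed beside PEO-IAA for 16 probe sets, among them AT3G25930 (3.27), AT5G04960 (2.72), AT1G30870 (2.62), EXPA18 (1.78) and AT4G30170 (1.32), as log2 differences. Of 100 random splits of these arrays 5 gave as many, the real one included, and the highest other gave 155. The splits mixed IAA arrays with others, so this share neither excludes chance nor speaks for it. Over the 337 probe sets called with IAA, the lowest median residual SD of another split was 0.329, against 0.256 in the real split. A count far above the real one points to a structure of the samples. The split with 155 had put the 3 arrays with 1 µM IAA together in the place of mock, so the effect of IAA itself entered its interaction. The responses to PPBo and kynurenine, measured on different replicate sets, differed for 4 probe sets.

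For the comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. The other splits also mix the arrays of both groups, so a real difference widens their residual spread and makes calls rarer. Their low counts therefore do not speak against chance. The real count and the highest of the other splits were 337 and 0 for 1 µM IAA, 1 and 0 for kynurenine, 104 and 0 for PEO-IAA, 170 and 0 for PEO-IAA plus IAA, 206 and 1 for PEO-IAA plus IAA against PEO-IAA, 58 and 1 for PEO-IAA plus IAA against IAA and 630 and 1 for PEO-IAA against IAA. For opposite calls, 1 of 100 random splits, the real one, gave as many, with 16 against 0 for PEO-IAA and 1 against 0 for kynurenine. This leaves open whether chance can be excluded, since the random splits mixed IAA arrays with others: over the 337 probe sets called with IAA their median residual SD had a median of 0.431 for PEO-IAA and 0.430 for kynurenine, against 0.256 in the real split, which makes calls rarer. The kynurenine count is GH3.3 alone and was 0 without mock replicate 2 or 3.

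The third 1 µM IAA array differed from the others in control probe sets that the comparisons do not use. Its GAPDH 3′ to 5′ ratio was 24.4, against at most 2.05 on the other 22 arrays, its mean log2 spike-in signal was 11.1, against 8.40 to 10.2, and its 25S rRNA signal was 40919, against 6198 to 9336. Degraded or scarce RNA is a candidate explanation that these values fit. A wrongly labelled array without IAA is argued against by the 6 core genes, which averaged 3.03 above mock on the log2 scale. An exchange with another IAA-treated sample was not tested. A mixture as the main source of the third array's deviation is argued against by correlations across probe sets. The highest with the effects of kynurenine, PEO-IAA, PPBo and 100 nM IAA was 0.0747, and the highest with the differences of all 8 other groups from a 1 µM IAA array was 0.0951. A small admixture stays open. No biological explanation was tested.

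The 3 tested genes of the detoxification list were higher with PEO-IAA. The lowest log2 change of the 3 genes with any array of the contrast left out was 2.12, and their median after quantile normalization was 2.71, which argue against a single array and against scaling. When IAA was added to PEO-IAA the median of the 3 genes changed by -0.30, so a response to the compound apart from auxin action may account for the pattern in these genes. This is a hypothesis, found and tested on the same data. GSTU26, outside the list, was called down when IAA was added to PEO-IAA (-1.07). That call ended in 2 of 7 fits with 1 array left out.

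The PPBo plus IAA arrays, labelled 1 µM IAA, resembled 100 nM IAA. Their mean log2 over the 6 core genes differed from that of the 100 nM IAA arrays by -0.23, and from that of the 1 µM IAA arrays, each relative to its own mock, by -1.36. An added dose of 100 nM could give this, and so could a lower level reached with 1 µM with PPBo or on these arrays. Over these genes PPBo alone was at -1.80, PPBo plus IAA at 1.85 and 1 µM IAA at 3.21. Counted from PPBo alone, the response to added IAA was thus not weaker than that to 1 µM IAA over mock. The difference of -1.36 includes the lowering by PPBo itself. The explanations cannot be told apart, because no array of replicates 4 and 5 holds 1 µM IAA alone.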

How the results depend on the processing

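The tests of leaving out the third IAA array from every contrast, of that with the replicate block, and of array quality weights were chosen after seeing the data. All other alternatives were planned. Of 301 values for counts of a contrast 177 stayed within 1.5 times, and of 946 for gene lists 876 kept direction and side of the threshold, 69 lost the call and 1 turned. Of 4208 for named genes 3789 kept both, 393 lost the call, 26 gained it and 0 turned direction in the limma fits. Of 60 for correlations across genes 50 moved by less than their spread over left-out arrays and 10 by more. Besides the counts given here, the replicate block moved no count by over 1.5 times. The core list, where called, kept its direction and its call under all alternatives run, except for kynurenine, PEO-IAA plus IAA against IAA and the IAA responses, as given. Leaving out an array of replicates 4 or 5 leaves 1 in its group, which is assumed to vary like the others. No scaling alternative moved a median of all probe sets by over 0.1. Without detection calls, low signals set the limit on what could be measured.

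With a 2-fold minimum, counts were 190 (1 µM IAA), 106 (PEO-IAA plus IAA), 124 (PEO-IAA plus IAA against PEO-IAA), 329 (PEO-IAA against IAA) and 9 (opposite calls with PEO-IAA). With the filter at the 50th percentile, counts were 218 (1 µM IAA), 60 (PEO-IAA), 128 (PEO-IAA plus IAA against PEO-IAA), 7 (the interaction), 387 (PEO-IAA against IAA), 31 (100 nM IAA), 36 (PPBo), 85 (PPBo plus IAA), 59 (PPBo plus IAA against PPBo) and 11 (opposite calls with PPBo). There the core list for PEO-IAA plus IAA against IAA had an adjusted p of 0.0565. There the Aux/IAA list for the IAA responses turned direction (adjusted p = 0.971), with fewer genes tested. There the core list for the IAA responses had an adjusted p of 0.246. With only arrays of the same replicate set, counts were 191 (1 µM IAA), 0 (kynurenine), 59 (PEO-IAA), 74 (PEO-IAA plus IAA), 111 (PEO-IAA plus IAA against PEO-IAA), 29 (PEO-IAA plus IAA against IAA), 6 (the interaction), 396 (PEO-IAA against IAA), 297 (100 nM IAA), 377 (PPBo), 640 (PPBo plus IAA) and 397 (PPBo plus IAA against PPBo). With only the groups of the contrast, counts were 55 (1 µM IAA), 0 (kynurenine), 54 (PEO-IAA), 50 (PEO-IAA plus IAA), 84 (PEO-IAA plus IAA against PEO-IAA), 0 (PEO-IAA plus IAA against IAA), 1 (the interaction), 145 (PEO-IAA against IAA), 480 (100 nM IAA), 286 (PPBo), 572 (PPBo plus IAA), 284 (PPBo plus IAA against PPBo) and 1 (the PPBo and kynurenine responses). There the core list for kynurenine had an adjusted p of 0.0793. With the replicate block, counts were 903 (1 µM IAA), 121 (PEO-IAA plus IAA against IAA), 1090 (PEO-IAA against IAA) and 1 (the IAA responses). All of these use the 1 µM IAA group, whose arrays did not pair with mock by number. The block lowers the shared spread through other groups without describing this group, so these counts do not show that more changed. The same limit holds for block counts with that group when an IAA array is also left out, given below. With mock replicates 1 to 5 as 1 control, counts were 545 (1 µM IAA), 2 (kynurenine), 160 (PEO-IAA), 297 (PEO-IAA plus IAA), 119 (100 nM IAA), 151 (PPBo) and 272 (PPBo plus IAA). With the block and without the third IAA array, counts were 1744 (1 µM IAA), 4 (kynurenine), 315 (PEO-IAA), 611 (PEO-IAA plus IAA), 540 (PEO-IAA plus IAA against PEO-IAA), 395 (PEO-IAA plus IAA against IAA), 227 (the interaction), 1480 (PEO-IAA against IAA), 201 (100 nM IAA), 240 (PPBo), 512 (PPBo plus IAA), 277 (PPBo plus IAA against PPBo), 12 (the IAA responses), 32 (the PPBo and kynurenine responses), 4 (opposite calls with kynurenine), 48 (opposite calls with PEO-IAA), 72 (opposite calls with PPBo) and 4 (opposite calls with all 3). With array weights, counts were 779 (1 µM IAA), 9 (kynurenine), 249 (PEO-IAA), 362 (PEO-IAA plus IAA), 106 (PEO-IAA plus IAA against IAA), 461 (100 nM IAA), 287 (PPBo), 639 (PPBo plus IAA), 245 (PPBo plus IAA against PPBo), 19 (the IAA responses), 56 (the PPBo and kynurenine responses), 6 (opposite calls with kynurenine), 34 (opposite calls with PEO-IAA), 61 (opposite calls with PPBo) and 4 (opposite calls with all 3). With a pseudocount of 1.89, counts were 0 (kynurenine), 0 (opposite calls with kynurenine) and 0 (opposite calls with all 3). Without the filter, counts were 2 (kynurenine), 2 (opposite calls with kynurenine) and 2 (opposite calls with all 3). With a pseudocount of 30.2, counts were 1 (the IAA responses).

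Leaving out 1 array gave 196 to 821 (1 µM IAA), 0 to 1 (kynurenine), 64 to 159 (PEO-IAA), 64 to 293 (PEO-IAA plus IAA), 111 to 333 (PEO-IAA plus IAA against PEO-IAA), 28 to 102 (PEO-IAA plus IAA against IAA), 9 to 23 (the interaction), 391 to 1083 (PEO-IAA against IAA), 12 to 71 (100 nM IAA), 10 to 114 (PPBo), 59 to 261 (PPBo plus IAA), 48 to 141 (PPBo plus IAA against PPBo), 0.00551 to 0.0550 (the core list for the IAA responses), 3 to 7 (the PPBo and kynurenine responses), 0 to 1 (opposite calls with kynurenine), 6 to 23 (opposite calls with PEO-IAA), 5 to 33 (opposite calls with PPBo) and 0 to 1 (opposite calls with all 3). Apart from fewer tested probe sets or fewer arrays, the cause was not tested.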

Other observations

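The tests of peroxidases and of probe sets called with IAA were chosen only after the results were seen.

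Class III peroxidases, enzymes that act on the cell wall, fell as a list with 1 µM IAA (limma's fry, adjusted p = 7.40e-05 as the one list in its family), with 3 down, 2 up and 32 of 37 uncalled, and with 100 nM IAA (adjusted p = 0.00671), with 3 down and 1 up. The list was drawn up after falls among its members had been seen, so it is not independent evidence of its direction. AT5G14130 rose by 1.73 with 1 µM IAA, beside AT3G01190, AT4G30170 and AT4G11290, which fell. With kynurenine (adjusted p = 0.674), PEO-IAA (0.708) and PPBo (0.251) the list did not pass.

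Of the families picked by symbol, those of 14 expansins and of 6 xyloglucan endotransglucosylase/hydrolases passed as lower on balance with PEO-IAA (both adjusted p = 0.0216), though limma called 3 and 0 of their members. With 1 µM IAA none of the 7 passed, with 33 UDP-glycosyltransferases and 12 glutathione S-transferases at 0.137, 14 expansins at 0.782, 6 xyloglucan endotransglucosylase/hydrolases, 12 CYP71B cytochromes P450 and 75 organelle-encoded transcripts at 0.375 and 7 RALF-like peptides at 0.782. With PEO-IAA against IAA the sets of UDP-glycosyltransferases (0.00364) and glutathione S-transferases (0.00153) passed as higher on balance, calls lost with an estimated correlation (both adjusted p = 0.103 with an estimated correlation). Among fixed lists not described, those for photosynthesis markers, the circadian clock, stress, hypoxia and reference genes did not pass with 1 µM IAA, at adjusted p = 0.520, 0.672, 0.991, 0.839 and 0.991.

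A hypothesis was that auxin already in the seedling keeps IAA-responsive genes at their mock level, so that PPBo would shift them the other way. The 145 probe sets called up with 1 µM IAA were lower with PPBo as a set (limma's fry, adjusted p = 5.94e-05 as a single test, median log2 change -0.26), and 103 of them were lower, as were 120 of the 192 called down, shares not tested against each other. Of those called up 18 were called down and 1 up with PPBo, and of those called down none passed either way (limma, also adjusted over the set alone), with means of -0.45 and -0.13. Endogenous auxin may keep those called up at their level. PPBo was measured on other arrays with a separate mock. The 192 probe sets called down with 1 µM IAA had a median of -0.08 with PPBo (adjusted p = 0.433 as a single test), which does not decide whether endogenous auxin keeps them down.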
